A study of Homo sapiens with 5 samples.

How the data were processed

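Total RNA of 786-O clones had been labelled with Cy3 and hybridised to single-colour Agilent arrays of design 026652, whose annotation used the hg18 build, per the file headers. The submitters' processing notes name Agilent Feature Extraction, and the version was 10.7.3.1 per the file headers. The deposited scanner tables gave processed signal intensity per spot, which the authors' scanner software had subtracted for background and detrended across the slide but not normalized between arrays, per the file headers. They also held median spot and local background intensity and flags for spots well above background, saturated or non-uniform. The authors' deposited value table held log2 values for 22887 probes. Set against the scanner values, each of its rows was centred on its median over the arrays, after a scaling like the 75th percentile (r = 1.0 in every column). Column medians were 0.0441 for vector control 2 and 0.0 for the others. The rule by which its probes were selected is not given in the sources used here.

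Each array held 44495 spots, of which 1377 were controls and were left out. Spots of a probe were averaged on the log2 scale (999 probes were printed 10 times), and 31 probes flagged as outliers on an array were left out, which left 34096. No spot was saturated. Signals were expressed as log2 of the processed signal minus the array's 75th percentile over non-control probes. A gene was tested where its probe was well above background on at least 2 of the 5 arrays, and the probe with the highest mean signal stood for genes with several. The scanner tables named probes by sequence accession, so symbols came from an NCBI RefSeq gene table of assembly GRCh38.p14, which was used for names and for the order of genes only. It gave 1 symbol to 24804 of the 34096 probes (72.7%) and none to 9292, and 13544 of the 17435 tested genes had a symbol. No coordinates are given because the builds differ.

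Groups followed the labels, with 3 WDR20 clones and 2 samples of 1 vector clone, and the main comparison fitted group alone over the 5 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Changes are clones minus vector. Where a probe was not well above background on any array of a group, a bound was computed. It sets the mean of the brighter group against the mean, over the dim arrays, of the higher of the probe's own signal and the lowest signal among probes well above background. Before the data were examined, 31 gene lists were fixed and tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, a rotation test. Members were also adjusted over the list alone. Fry called 0 lists in one direction and 19 for change in either direction, and camera with an estimated correlation called 0.

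The genes named were chosen by a rule fixed beforehand. It took WDR20, then the 8 largest rises and 8 largest falls among changed genes well above background on all 5 arrays with the clones on one side of both vector arrays. It added the 4 genes with the lowest p in each direction among those above background in one group only. From each list it took up to 3 members, changed ones first and then those with the lowest p, or the lowest p alone where none changed. Genes without a plain symbol, open reading frames, long non-coding RNAs, XIST and Y-linked genes were not named. A gene that the rule selected is not reported here.

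The procedure was tested on simulated data with the real arrays' levels and spread over 17435 genes. It recovered 2% of 50 genes changed by 1 on the log2 scale, 46% of those changed by 2, 76% by 4 and 96% by 6, with 7 false calls. Changes of 2-fold were therefore mostly out of reach with 5 arrays. The simulated noise was independent between arrays and between genes and held no difference between clones. The 7 false calls thus do not cover genes that differ because of the 1 vector clone. Alternatives covered other scalings (quantile, median, 75th percentile over probes above background on all arrays), the authors' value table, filters on dim probes, and the treatment of several probes per gene. They also covered variance models, the slide as a block, the mean of the vector arrays as 1 sample, stricter or fold-based criteria, and leaving out each array. A normexp background correction (offset 50) was planned on mean spot signals, but was run on median spot signals, the column present in the tables. A common floor on dim signals was added after the data were seen. Figures were drawn with matplotlib 3.10.9 from values computed in Python 3.11.15.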

Results

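The data set profiled messenger RNA in 786-O, a human kidney cancer line that lacks a working VHL tumour suppressor gene. Cells had been stably transfected to overexpress WDR20, a WD-repeat protein that binds the deubiquitinases USP12 and USP46, or had received the empty vector. The question stated for the series was how WDR20 overexpression alters the expression profile of the line. RNA from 3 separate WDR20 clones and 2 replicate samples of 1 vector clone was hybridised to 5 single-colour Agilent arrays. Between 58.65% and 63.14% of the 34096 probes kept were well above background on each array. The 75th percentile of the processed signal was 1342.6 and 857.8 on the vector arrays and 1840.4, 1676.6 and 1909.1 on WDR20 clones 1, 2 and 3. Vector control 1 shared a slide and a scan with the 3 clones, and vector control 2 was alone on a second slide. The labels do not say whether both vector samples came from separate cultures, so p-values measure the spread between these samples, part of which may be technical. With 1 vector clone, a difference between that clone and the WDR20 clones cannot be separated from an effect of WDR20. Such a small number of arrays also limits the precision of each value.

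WDR20 itself did not differ detectably between the groups. Its 1 probe, which was well above background on all 5 arrays, gave normalized log2 signals of -2.24 and -1.67 in the vector controls. The corresponding signals were -2.10, -1.87 and -2.09 in the samples labelled WDR20 clones 1, 2 and 3. The log2 change was -0.06 ± 0.27 (SE, 3 clones against 2 vector arrays; limma adjusted p = 0.929). On the first slide alone it was 0.23 (adjusted p = 0.791). Whether this probe lies within the transfected sequence is not given in the sources used here, and a probe outside it would not register the transgene. The overexpression stated in the labels was therefore not seen at this probe. The groups below keep the labelled names.

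Among 17435 genes tested, 85 were higher and 45 were lower in the WDR20 clones at an adjusted p under 0.05 (limma, two-sided). The clearest changes were genes well above background in one group and in no array of the other. XK, which encodes a membrane protein linked to the Kell blood group antigen, was at least 43.5-fold higher in the clones, the potassium channel gene KCNK6 at least 15.4-fold, the glycine transporter gene SLC6A9 at least 16.2-fold and EYA2, a transcriptional coactivator, at least 9.36-fold. In the opposite direction, the zinc finger gene ZNF22 was at least 140.1-fold lower, the phospholipase-like gene PLBD1 at least 49.0-fold, LRRC34 at least 45.2-fold and POGLUT3, which encodes a protein O-glucosyltransferase, at least 33.1-fold. Each bound sets the mean of the bright group against the lowest signal that counted as well above background on the dim arrays. With a common floor, the highest of these lowest signals, the 8 changes were smaller, between 6.56-fold and 99.9-fold, and with normexp background correction they lay between 3.21-fold and 46.6-fold. All 8 kept their calls in both, but the size of these changes depended on how dim signals were treated. The adjusted p of these 8 genes lay between 0.00034 and 0.0022, and each stayed past the threshold when any 1 array was left out (adjusted p up to 0.036). Of the 130 changed genes, 45 were well above background in all 3 clones and in neither vector array, and 25 in both vector arrays and no clone. Y-linked genes made up 10 of the 85 higher genes and 0 of the 45 lower genes.

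Among changed genes measured above background on all 5 arrays, PICK1, which encodes a PDZ-domain scaffold protein, had the largest rise with all arrays and the brightest probe per gene. It went from -2.98 ± 0.09 (SD, n = 2) in the vector controls to 2.06 ± 0.26 (SD, n = 3) in the clones, a 33.0-fold difference. CYB5A, the gene for cytochrome b5, rose 27.1-fold (log2 change 4.76 ± 0.38 SE), and a second CYB5A probe gave 5.15, above the 5.04 of PICK1. Without vector control 2, CYB5A was also ahead (5.32 against 4.98). The gene for the matrix protein fibronectin, FN1, rose 13.2-fold (3.73 ± 0.32 SE), and ZNF630 rose 12.3-fold (3.62 ± 0.31 SE; second probe 2.57). These 4 genes stayed past the threshold without any single array. MAOA, which encodes monoamine oxidase A, rose 17.2-fold, FBXL16 14.9-fold, DHX58, a member of the RIG-I-like receptor family, 13.8-fold and PLEK, the gene for pleckstrin, 11.5-fold. For these last 4 the changes stayed large whichever array was left out (log2 change 3.12 to 4.598), but the calls depended on single arrays. All lost their calls without vector control 1 (adjusted p = 0.100, 0.0944, 0.0899 and 0.0899) and without vector control 2 (0.199, 0.338, 0.257 and 0.295). FBXL16, DHX58 and PLEK also did so without clone 1 (0.0669, 0.0694 and 0.0579), and MAOA without clone 2 (0.0898). With the common floor their changes were unmoved but the calls were lost (adjusted p = 0.134 to 0.143). Other settings did move the sizes. Over 19 alternatives the lowest log2 changes of MAOA, FBXL16, DHX58 and PLEK were 2.82, 3.07, 3.28 and 2.41.

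Among the falls measured above background on all 5 arrays, TENM2, which encodes a teneurin cell-adhesion protein, fell 21.4-fold (log2 change -4.42 ± 0.46 SE; second probe -4.69). WASF3, an actin regulator, fell 18.4-fold (-4.20 ± 0.36 SE), and more than TENM2 without vector control 1 (-4.54 against -3.79). The fall of ETNK2, an ethanolamine kinase gene, was 13.6-fold (-3.76 ± 0.45 SE). CBS, the gene for cystathionine beta-synthase, fell 5.39-fold, from 3.08 ± 0.02 (SD, n = 2) to 0.65 ± 0.20 (SD, n = 3). SOWAHD fell 4.86-fold, ARHGAP6 4.72-fold, CIMAP1B 4.58-fold and the glutamate transporter gene SLC1A3 3.76-fold. All 8 stayed lower in every fit that left out an array, with log2 changes of -5.05 to -1.65, but none kept its call in every one. The 8 that passed with all arrays came to 2 without vector control 1 and 0 without vector control 2, where their adjusted p reached 0.257. Without clones 1, 2 and 3 they came to 4, 4 and 5. With the common floor, which left their changes unmoved, only WASF3 and CBS kept their calls. Normexp took CIMAP1B to -1.29 (adjusted p = 0.0814). Over 19 alternatives the smallest falls of WASF3, ETNK2 and ARHGAP6 were -2.98, -2.74 and -1.46. Those of TENM2, CBS, SOWAHD and SLC1A3 were -3.79, -2.30, -1.64 and -1.55.

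**Figure D1:**
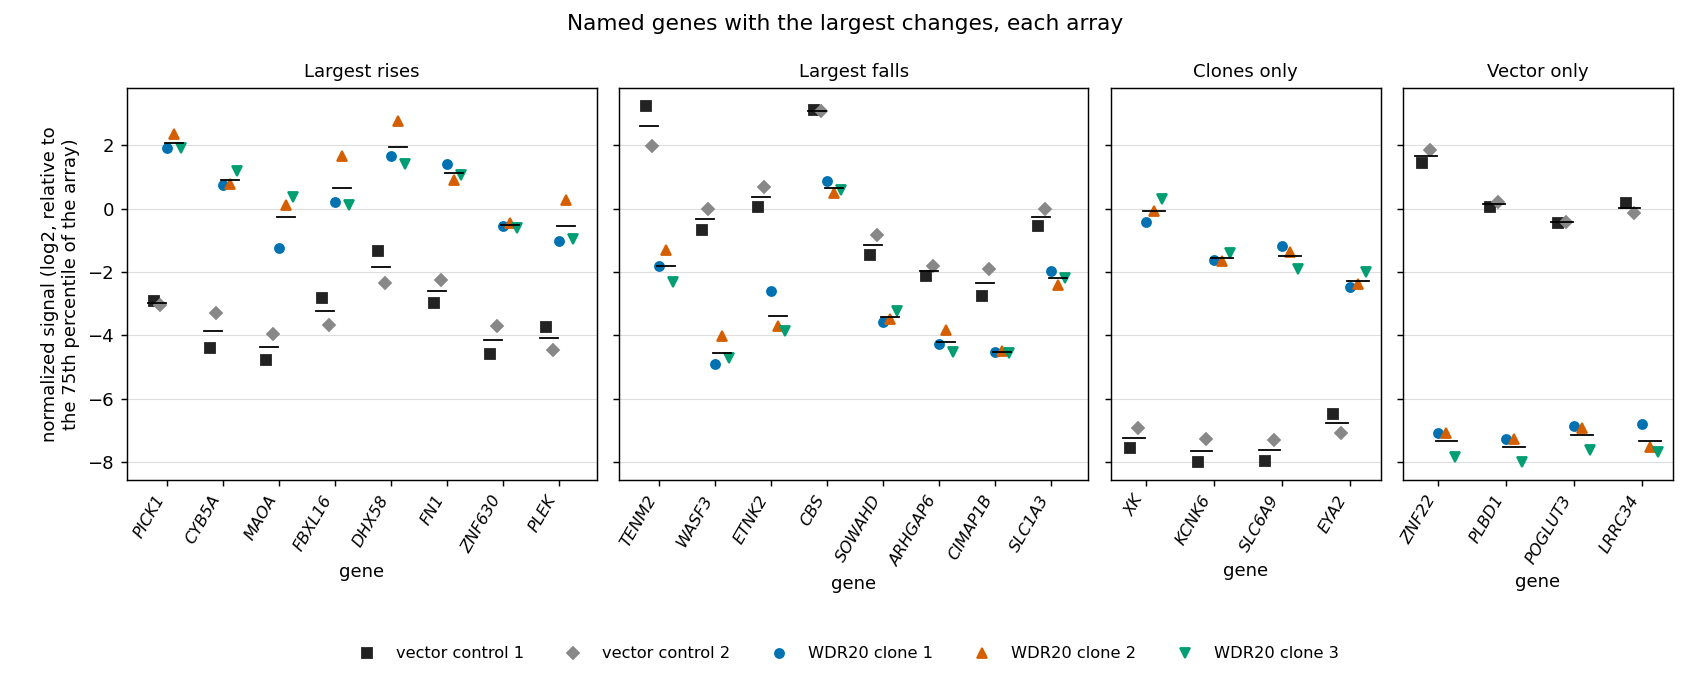
Normalized signal (log2, relative to the 75th percentile of each array) of the named genes, with 1 symbol per array and a short line at each group mean. The 3 WDR20 clones lie on one side of both vector controls for every gene shown, as for PICK1 at 2.06 against -2.98, and in the panels headed clones only and vector only the low values are signals not well above background.

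All 130 changed genes had the 3 clones on one side of both vector arrays, and the smallest change among them was 3.11-fold. Over all tested genes the groups did not overlap for 35.4%. Chance gives 20% only if all arrays are exchangeable. Both vector arrays are of the same clone and may group together without any effect of WDR20. The excess over 20% therefore cannot decide whether WDR20 had an effect. The median log2 change of all tested genes was -0.09. The count of changed genes depended on single arrays. It was 62 without vector control 1, 41 without vector control 2 (the fit with slide as a block, hence the first slide alone, with the lone vector array assumed to vary as the clones do), 82 without clone 1, 99 without clone 2 and 178 without clone 3, where 75.8% were higher against 65.4% with all arrays. The authors' value table, in the same fit, gave 27 higher and 22 lower.

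The vector samples also differed from each other. Their root mean square log2 difference over tested genes was 0.74, with 2486 genes at least 2-fold apart. They were hybridised on separate slides. Pairs of WDR20 clones differed by 0.64, 0.64 and 0.78. Vector control 1 stood 0.80, 0.91 and 0.79 from clones 1, 2 and 3, and vector control 2 stood 0.97, 1.08 and 0.97 from them. By the count of genes at least 2-fold apart, the vector pair (2486) exceeded every pair of clones (1254 to 1888). It also exceeded vector control 1 against clones 1 and 3 (1862 and 1556), but not against clone 2 (2590). Vector control 2 differed from clones 1, 2 and 3 at 3680, 4327 and 3595 genes. No test was made of these 10 pairs.

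**Figure D2:**
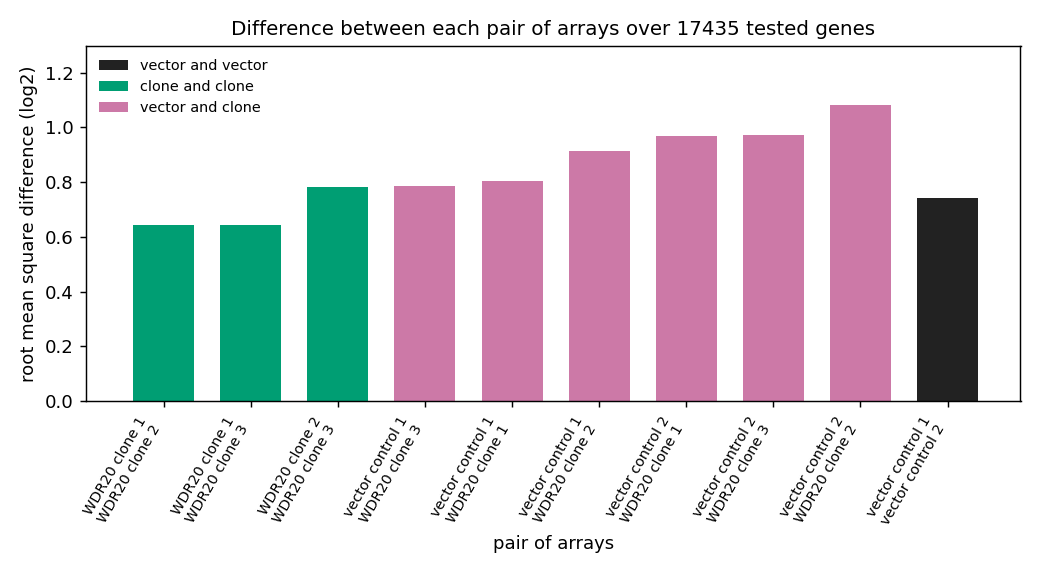
Root mean square log2 difference over the 17435 tested genes for each of the 10 pairs of arrays, coloured by the kind of pair. Vector control 1 lies 0.79 from clone 3, close to the 0.74 between the vector controls and the 0.78 between clones 2 and 3.

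Interferon response genes were the list that stood highest in the WDR20 clones. All 25 tested members had a positive change, with a median log2 change of 1.502, and 1 rose past the threshold over all genes while 13 rose when adjusted over the list alone. HERC5, the ligase that attaches the ubiquitin-like protein made by ISG15, was called higher, with a log2 change of 4.21 ± 0.34 SE. It was well above background on 1 of the 2 vector arrays, so the size is uncertain (3.93 with the common floor and 2.43 with normexp for HERC5). USP18, which reverses that modification, had a change of 1.502 ± 0.31 SE and the RNA sensor gene IFIH1 1.90 ± 0.44 SE, neither past the threshold over all genes (adjusted p = 0.141 and 0.173). Against the mean of the vector arrays the list median was 1.301 in clone 1, 2.58 in clone 2 and 0.78 in clone 3, while the vector arrays lay at 0.25 and -0.25. The list passed limma's camera with a preset inter-gene correlation of 0.01 (adjusted p = 3.8e-12 over 31 lists), but not with an estimated correlation (adjusted p = 0.699). On the first slide alone the median was 1.23 (camera adjusted p = 4.1e-08).

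NF-kB targets and cytokines were also higher, with 14 of 18 tested members positive and a median log2 change of 0.89. Against the mean of the vector arrays the list median was 0.28 in clone 1, 0.55 in clone 2 and 1.12 in clone 3, and the vector arrays themselves lay at 0.24 and -0.24, so clone 1 was close to vector control 1. In this list 1 member rose past the threshold over all genes and 2 when adjusted over the list alone. CSF2, which encodes granulocyte-macrophage colony-stimulating factor, was called higher, with a change of 4.59 ± 0.36 SE. CSF2 was also well above background on only 1 vector array, and its change was 3.26 with normexp. The chemokine genes CXCL1 and CXCL2 had changes of 2.39 ± 0.50 SE and 0.94 ± 0.32 SE (adjusted p = 0.141 and 0.282). CXCL1 differed between the vector arrays, and without vector control 1 its change was 3.27 (adjusted p = 0.0325) but without vector control 2 it was 1.504 (adjusted p = 0.212). With normexp CXCL1 passed (0.0266). The camera adjusted p of the list was 0.00014, against an adjusted p of 0.699 with an estimated correlation, and on the first slide alone the median was 0.43 (camera adjusted p = 0.0015). Antigen presentation genes had 10 of 12 members positive and a median of 0.47, with none past the threshold over all genes or adjusted over the list alone. HLA-F had the lowest p, at 0.79 ± 0.27 SE (adjusted p = 0.282). The list passed camera (adjusted p = 0.0230), but not with an estimated correlation (adjusted p = 0.699), nor without vector control 1 (0.0654), clone 1 (0.0674) or clone 2 (0.0587), where its medians were 0.43, 0.49 and 0.28. Its first-slide median was 0.32 (camera adjusted p = 0.0346).

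Genes of growth and division lay lower in the WDR20 clones. All 28 cytosolic ribosomal protein genes had a negative change, with a median log2 change of -0.55, and none passed over all genes or adjusted over the list alone. RPL30 had the lowest p, at -0.98 ± 0.28 SE (adjusted p = 0.230). The camera adjusted p was 1.1e-06, against an adjusted p of 0.699 with an estimated correlation, and quantile normalization ended the call (0.0933), with the median at -0.18. Mitosis genes were negative in 22 of 23 members, with a median of -0.60 and none past either threshold. The kinesin gene KIF20A had -0.87 ± 0.26 SE (adjusted p = 0.241). DNA replication genes were negative in 23 of 26 members, with a median of -0.52 and none past either threshold. The gene of the DNA polymerase alpha catalytic subunit, POLA1, had -1.10 ± 0.25 SE (adjusted p = 0.166). Camera gave adjusted p = 0.00050 for mitosis and 0.00044 for DNA replication, and with an estimated correlation the adjusted p was 0.721 and 0.699. Without vector control 1 both calls were lost (0.0853 and 0.0654), with medians of -0.39 and -0.64. Without clone 2 both calls held, but the mitosis median moved most, to -0.32, and that of DNA replication was -0.41. On the first slide alone the medians were -0.39 for ribosomal proteins, -0.56 for mitosis and -0.45 for DNA replication, with camera adjusted p of 1.1e-05, 4.0e-05 and 7.3e-05.

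Cholesterol synthesis genes were negative in 20 of 22 tested members, with a median log2 change of -0.36. None fell past the threshold over all genes and 2 fell when adjusted over the list alone. SCD, which encodes the fatty acid desaturase, had -2.37 ± 0.42 SE (adjusted p = 0.0895). It passed with a trended, robust variance (0.0398) and with normexp background correction (0.0192). The camera adjusted p was 0.0170, against an adjusted p of 0.721 with an estimated correlation. The call was lost without vector control 1 (0.946), without clone 1 (0.0560) and with quantile normalization (0.0792), where the medians were 0.03, -0.30 and -0.23. The vector arrays themselves lay 0.25 above and 0.25 below their mean for this list, and on the first slide alone its median was -0.68 (camera adjusted p = 2.2e-07).

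**Figure D3:**
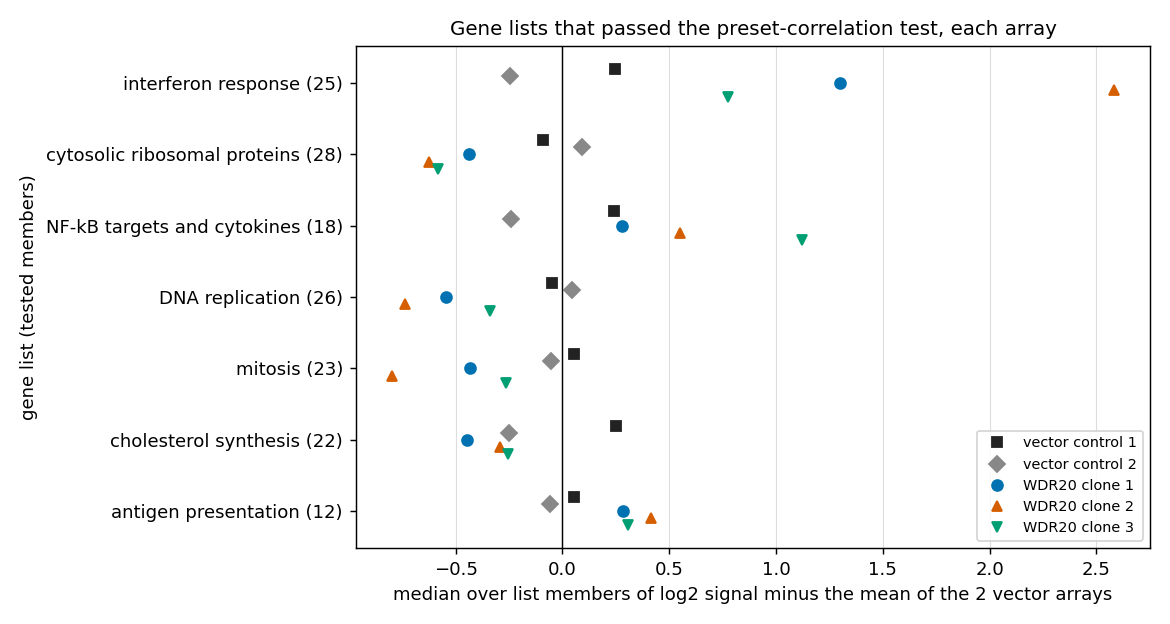
Median over the tested members of each list of the log2 signal minus the mean of the 2 vector arrays, with 1 symbol per array, for the 7 lists that passed camera with the preset correlation. The interferon median spans 0.78 to 2.58 across the clones, and for cholesterol synthesis vector control 2 lies at -0.25, beside clone 3 at -0.25 and clone 2 at -0.29.

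No other list passed camera, with adjusted p from 0.107 to 0.995. Those with a member past the threshold over all genes are given first. Mesenchymal and matrix genes had 2 of 26 members higher, FN1 and the fibrillin gene FBN1, the latter at least 2.27-fold, and 3 higher when adjusted over the list alone; THBS1 had 1.13 ± 0.25 SE (adjusted p = 0.155). The list median was -0.05. In glycolysis (median -0.09), 1 of 19 members was higher over all genes and adjusted over the list alone. That member was HK2, the gene for hexokinase, which rose 3.78-fold, while PGAM1 and ALDOC had -1.07 ± 0.32 SE and -1.07 ± 0.38 SE (adjusted p = 0.242 and 0.295; ALDOC well above background in 2 of 3 clones). Stromal and pericyte markers (median 0.14) had 1 of 7 members lower by both counts. It was PDGFRB, the receptor for platelet-derived growth factor, at least 8.49-fold lower and not well above background in any clone, while DCN, well above background on 1 vector array and in 1 clone, and RGS5 had 0.65 ± 0.49 SE and 0.17 ± 0.32 SE. Of 4 cancer-testis antigen genes tested (median -0.06), SSX1 was at least 2.07-fold higher and the only one past either threshold, and MAGEA6 and CTAG2 had changes of -0.83 and -0.14 (adjusted p = 0.703 and 0.871). MAGEA6 was well above background on 1 vector array and in 1 clone, and CTAG2 in 2 of 3 clones. PDGFRB, HERC5 and CSF2 stayed past the threshold without any single array. FBN1 was called only without vector control 1, HK2 only without clone 3, and SSX1 only without clone 2 or clone 3, and otherwise these 3 had an adjusted p of 0.0510 to 0.234. All 3 stayed higher throughout, HK2 with log2 changes of 1.80 to 2.06. The bounds of FBN1 and SSX1 rested on the floor. With a common floor their changes were 1.59-fold and 1.45-fold and neither was called (adjusted p = 0.217 and 0.478), nor was either with normexp (both 0.330). PDGFRB kept its call in both, at 6.05-fold with the floor.

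In the other lists no member passed over all genes. Known partners of the WDR20 complex had 6 of 7 members negative, with a median of -0.38 and none past the threshold when adjusted over the list alone; USP46 had the lowest p, at -0.87 ± 0.23 SE (adjusted p = 0.207). The neighbours of WDR20 on 14q32 had a median of -0.03 over 16 members and none past the threshold adjusted over the list alone, with KLC1 at 0.95 ± 0.44 SE. Hypoxia-inducible factor targets had a median of 0.02 over 25 members, with 3 higher and 2 lower when adjusted over the list alone and VEGFA at 1.495 ± 0.26 SE (adjusted p = 0.0813; 0.0417 with the trended, robust variance and 0.0491 with normexp). Proximal tubule markers had a median of 0.37 over 18 members, with 4 higher and 1 lower adjusted over the list alone, but a median of -0.08 without vector control 2. Anti-apoptotic genes had 2 of 10 members higher adjusted over the list alone, with a median of 0.33 and BCL2L2 at 0.92 ± 0.23 SE. Adjusted over the list alone, YAP targets had 1 of 18 members higher (median -0.23; F3, the gene for tissue factor, at 1.69 ± 0.26 SE, adjusted p = 0.0557). Quantile and median scaling brought F3 past the threshold (adjusted p = 0.0490 and 0.0498). So did the 75th percentile over probes above background on all arrays (0.0421) and testing only such probes (0.0482). Normexp (0.0099) and the trended, robust variance (0.0215) did so too, and the other 13 of 19 alternatives did not. Metallothioneins had 1 of 7 members lower adjusted over the list alone (median -0.27; MT1G at -1.04 ± 0.27 SE, well above background in both vector arrays but in only 1 of 3 clones, and its change was -0.17 with the common floor).

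The remaining lists had no member past the threshold over all genes or adjusted over the list alone. Those with a positive median were ERK output (0.24 over 18 members; MYC at -1.08 ± 0.26 SE; 0.09 without clone 2 and 0.80 without vector control 1), immediate early genes (0.33 over 10; DUSP1 at -1.24 ± 0.34 SE), p53 targets (0.23 over 22; PLK3 at 0.94 ± 0.24 SE), NRF2 targets (0.12 over 14; AKR1B10 at 2.79 ± 0.87 SE) and epithelial genes (0.07 over 18; MUC1 at least 3.34-fold higher, or 2.34-fold with the common floor). A negative median was found for oxidative phosphorylation (-0.24 over 25, with SDHD at -0.92 ± 0.23 SE) and pro-apoptotic genes (-0.14 over 18, with BMF at 1.70 ± 0.44 SE). FOXO targets also had a negative median (-0.26 over 19, with TXNIP at 1.36 ± 0.33 SE). The ATF4 stress response (-0.15 over 16; DDIT3 at 0.92 ± 0.35 SE) and endoplasmic reticulum chaperones (-0.02 over 15; SDF2L1 at -0.65 ± 0.23 SE) belonged to the same set. So did endothelial markers (-0.63 over 3; CDH5 at -0.88 ± 0.35 SE), leukocyte markers (-0.08 over 13; LCP1 at -1.60 ± 0.55 SE) and the protocadherin beta cluster (-0.57 over 7; PCDHB2 at -1.27 ± 0.65 SE), whose median was 0.34 without clone 3. The sign of several medians rested on single arrays. It turned without vector control 1 for epithelial genes (-0.19) and endoplasmic reticulum chaperones (0.12). It turned without vector control 2 for immediate early genes (-0.02), pro-apoptotic genes (0.18), leukocyte markers (0.09) and metallothioneins (0.11). Medians of cancer-testis antigens, mesenchymal and matrix genes, stromal and pericyte markers, hypoxia-inducible factor targets and the 14q32 neighbours also changed sign in such fits. Some other medians kept their sign but moved. Without vector control 1, p53 targets stood at 0.03, YAP targets at -0.06 and NRF2 targets at 0.24. Without vector control 2, FOXO targets stood at -0.07 and anti-apoptotic genes at 0.14. Leaving out clone 3 brought ERK output, proximal tubule markers and NRF2 targets past the camera threshold (adjusted p = 0.0123, 0.0394 and 0.0431). Oxidative phosphorylation passed camera without clone 2 (0.0321) and with each probe tested on its own (0.0146). Without clone 3, AKR1B10 also passed (0.0487). The lists' medians and camera, which compares a list with the other genes, pointed in different directions for mesenchymal and matrix genes, cancer-testis antigens, pro-apoptotic genes, the 14q32 neighbours, the ATF4 response, endoplasmic reticulum chaperones, and stromal and pericyte markers.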

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

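The normexp correction on median signals and the common floor on dim signals were chosen after the data were seen, and normexp on mean signals was not run. With 130 changed genes in the reported fit, the count was 49 with the authors' value table, which held the probes of 65 of those genes, and 38 with a common floor on dim signals. It was 74 with no filter on dim probes, 53 with probes above background on all 5 arrays, 80 with array quality weights, 41 with slide as a block and 38 with the mean of the vector arrays as 1 sample. Without single arrays it ran from 41 to 178. An adjusted p under 0.01 left 55, and 2-fold with no test gave 1704. In the other scalings, background, probe and variance settings it lay between 127 and 168. Normexp called 150 genes, of which 76 were among the 130; the cause was not tested for the floor, normexp, filter and weighting results. The share of higher genes went from 65.4% to 55.1% with the value table. The spread between arrays (root mean square log2 difference) fell with normexp from 0.74 to 0.56 within the vector pair, from 0.92 to 0.65 between vector and clones and from 0.69 to 0.51 between clones. With probes above background on all arrays the last 2 were 0.72 and 0.53. WDR20 was not called in any of 19 alternatives, its log2 change running from -0.34 to 0.23. No called change reversed. Each named gene in each alternative was counted as 1 case. Calls were lost in 120 of 546 cases of genes called in the reported fit. They were gained in 14 of 675 cases of genes not called there. For gene lists, 23 of 147 were lost and 5 of 501 gained. No paired analysis was possible because the vector samples carry no replicate number that matches a clone. Below background, only bounds can be given, which applies to 75 of the 130 changed genes.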

Other observations

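All tests of the runs of neighbouring genes, the first-slide fit of changed genes, the counts of Y-linked genes and of genes on in 1 array of a pair, and the list medians under quantile normalization were chosen after results were seen. For the other tests of explanations, predictions were written beforehand, but the patterns they address came from the main results. None was written for the splits of the arrays or for the lists between the vector arrays. The protocadherin beta cluster differed among the WDR20 clones more than between the groups. Against the mean of the vector arrays, the median over its 7 tested members was -0.01 in clone 1, 0.83 in clone 2 and -2.02 in clone 3, with the vector arrays at 0.48 and -0.48. The interferon list had its highest median in clone 2 (2.58) and the NF-kB and cytokine list in clone 3 (1.12).

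Genes were also shifted in runs along chromosomes. With 12232 genes above background on all 5 arrays ordered by the reference, 234 blocks of about 50 neighbours were formed, and 7 had a median change above, and 10 below, that of any block in 1000 shuffled gene orders. All 7 lay on the chromosome that carries FN1, where each of the 15 blocks had a positive median (0.29 to 0.61), so the rise ran along the whole chromosome. The highest was the block from SMYD5 to RNF181, at 0.61 above the median of all genes on the log2 scale, with 0.56, 0.47 and 0.45 in clones 1, 2 and 3. The block from FN1 to AP1S3 stood at 0.49. The lowest was the block from LY96 to CPQ, at -0.56, with -0.65, -0.67 and -0.29 in the clones. These blocks were picked after their values were seen.

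For these runs, the correlation across genes between a gene's change and the mean change of its 10 nearest tested neighbours was 0.26 (Spearman), against at most 0.048 in shuffled orders; genes are not independent replicates. The second slide is argued against as the source, since on the first slide alone the correlation was 0.31. A candidate explanation is different chromosome content of the clones. The 0.26 was above the 0.15 found between the vector arrays. Pairs of WDR20 clones gave 0.34, 0.29 and 0.27, as they would if each clone carried its own gains and losses. The 0.15 was itself above every shuffled order (at most 0.038), although both vector samples are of 1 clone. Part of such a correlation may thus have another source. Regional co-regulation and a probe property shared by neighbours were not tested and stay open, and no DNA was measured.

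For the genes switched on or off between the vector clone and the WDR20 clones, the second slide is argued against as the whole cause, because the first slide alone called 41 genes, 39 of them among the 130. That fit had 1 vector array, which was assumed to vary as the clones do. All 130 kept their direction and at least a 2-fold difference on that slide, and 21 were 2-fold apart between the vector arrays, although a call already favours genes on which those arrays agree. A copy-number shift of the surrounding region is argued against as the general cause for the 99 changed autosomal and X-linked genes. Their 10 nearest neighbours well above background on all 5 arrays moved with them by a median of only 0.079 (upper quartile 0.22). The smallest called change was 1.64. Neighbours silent in 1 group were left out by that filter, and a change of single genes would not move 10 neighbours. Complete loss of a stretch and small gains or losses therefore stay open. Differences of the size seen between WDR20 clones fell short of the count. A WDR20 clone stood at least 8-fold from both others, themselves within 2-fold, at 40 genes at most, and vector control 1 stood so from pairs of clones at 73 to 99 genes. The margin was smaller between single arrays. Genes above background on only 1 array of a pair and at least 8-fold apart numbered 65 between the vector arrays, 78 to 125 between clones and 135 to 261 between vector and clone arrays. Y-linked genes were not in the copy-number test. Of 19 tested, 10 were among the 85 higher genes (52.6% called, against 0.69% of the other tested genes) and none was lower. On in all 3 clones and in neither vector array were 8 of the 19. These values go with a chromosome content that differs between the vector clone and all 3 WDR20 clones, as does the rise along the chromosome of FN1. No DNA was measured, so this was not tested and stays open. For the other changed genes an unusual vector clone and an effect of WDR20 both stay open, since 1 vector clone was profiled. The 10 splits of the 5 arrays into 3 and 2 are too few for a share under 0.05. The real split called 130 genes against 3 in the highest other. It sets both samples of 1 vector clone against the rest, so a difference of that clone alone would also give it the highest count.

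For the lower lists of growth and division, compression of bright signals on the brighter clone arrays would lower equally bright genes alike. The list medians lay lower still, which argues against compression as the whole cause only if list members vary independently. A share of compression stays open. Random lists of equally bright genes lay lower too, at a median of -0.30 for the ribosomal list, but the list median of -0.553 was below the lowest 2.5% of 10000 such lists (-0.44). So were mitosis at -0.603 (-0.36) and DNA replication at -0.524 (-0.34). Random lists hold unrelated genes, but the estimated correlation within these lists was 0.27, 0.51 and 0.31, so random lists spread too little. Between the vector arrays, the interferon, NF-kB and cholesterol lists also fell below such lists (percentiles 0, 0.14 and 0.02). The ribosomal, mitosis, DNA replication and antigen presentation lists did not (85.9, 18.4, 70.4 and 20.0). Quantile normalization, which removes differences in the signal distribution, took the ribosomal median to -0.18 and ended its call, mitosis to -0.43 and DNA replication to -0.35. Each stayed below the lowest 2.5% of equally bright lists under that scaling (-0.084, -0.23 and -0.21). A share from the second slide cannot be told apart, as the medians on the first slide, -0.39, -0.56 and -0.45, were smaller but kept most of their size. Slower growth of the WDR20 clones may be an explanation but was not measured, and a fast-growing vector clone would give the same values. A share from the runs of neighbouring genes was not tested for these lists and stays open.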
